A study of Schmidtea mediterranea with 4 samples.

How the data were processed

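Polyadenylated RNA from tail tissue of asexual Schmidtea mediterranea (strain CIW4), a freshwater flatworm that can regrow its whole body, was sequenced in 4 libraries. Per the labels' protocols, animals were kept at 20 °C, starved for at least 7 days and given 2 feedings with double-stranded RNA (dsRNA) at intervals of 3 days, RNA was purified with TRIzol, and each library was made from 2 µg of RNA with a VAHTS Universal V8 kit. Both groups are marked 10 dpf, an abbreviation that the labels do not spell out.

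The deposited table gives TPM (transcript abundance corrected for length), scaled by the authors so that each of its 4 columns sums to 1000000 over 36019 gene IDs. A batch effect had been taken out before deposit, per the name of the deposited table. The method, and which libraries formed a batch, are not given in the sources used here. SAMtools is named in the submitters' processing notes. The aligner, the counting tool, the annotation and the genome build are not given in the sources used here. The values hold no negative number. The table pairs its IDs with no gene names and no gene annotation was used here, so IDs are printed as they stand, at most 2 in each direction. For the same reason the level of nsf itself could not be looked up, and the 22 lists of marker and pathway genes fixed before the data were examined (neurons, neuropeptides, vesicle fusion, stem cells, muscle, gut and others) were not run.

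Libraries were grouped by their labels into EGFP RNAi (n = 2) and nsf RNAi (n = 2). The main test was limma 3.58.1 in R 4.3.3 (linear model and empirical Bayes moderation with an abundance trend) on log2(TPM + 1). It was run over the 19555 IDs with a mean of at least 1 TPM, with the replicate number as a block and Benjamini-Hochberg adjustment, and IDs with an adjusted p under 0.05 were called. Fold changes on this scale understate the change of low genes. The block was part of the design from the start, because taking a batch out of 4 libraries uses up 1 of the 2 residual degrees of freedom. It rests on the assumption that the batch taken out was the replicate number, which no source used here states. The titles of both replicate 2 libraries carry an unexplained suffix, -p. At 1 to 5 TPM the variance between replicate numbers was 0.60 times that of Poisson counts. The crossed split (EGFP RNAi replicate 1 with nsf RNAi replicate 2 against the rest) had 1.51 times. From 5 to 20 TPM these were 0.53 and 1.47, and from 20 to 100 TPM 0.80 and 1.61. At 100 TPM or more they were 2.30 and 2.49. The values below 100 TPM argue against the crossed split as the batch taken out. With the block 1 residual degree of freedom was left, that of the crossed split, and moderation across IDs raised the total to 5.83. The replicate numbers of the labels were not shown to mark a shared culture or day. The differences between replicates 1 and 2 in EGFP RNAi and in nsf RNAi correlated at -0.42 across IDs. Removing a batch common to both groups pushes this correlation down, so it does not settle whether the numbers pair the libraries. P-values of the main test measure the spread of the crossed split, moderated across IDs, and not the difference between replicates 1 and 2. This spread may be technical, since nothing in the labels says whether the replicates came from separate animals or cultures. An exact two-sided permutation test of 2 against 2 libraries cannot go below p = 0.33 and was not used for calls.

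A rule fixed before the data were examined limited IDs without gene names to 2 per direction among those past the test. Only SMED30019484 met it. Places left by too few calls went to the largest fold changes among IDs with a mean of at least 10 TPM whose groups did not overlap. That way of filling places was fixed beforehand for genes with names, and the rule did not state it for IDs without names. Where the test was not passed, values are given and no change is claimed.

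TPM does not by itself give the sequencing depth. Within each ID, however, the deposited TPM were whole numbers divided by a whole-number length and scaled by 1 factor per library. From the most frequent ratios between libraries, counts and lengths were recovered for 26185 of the 26187 IDs above 0 in 2 or more libraries (whole within 0.01, Python 3.11.15 with numpy 2.4.6). These counts are the ones behind the adjusted TPM, not the raw read counts. On 8000 simulated genes the recovery returned the exact counts for 96.4% of those recovered. The recovered counts summed to 7150314 and 9834847 in EGFP RNAi replicates 1 and 2, and to 7010071 and 7799982 in nsf RNAi replicates 1 and 2. They were used to describe depth, to simulate counting error and, as an alternative chosen after the data were seen, in limma's voom. Voom was looked at with no count filter, at a mean of at least 10 counts and at a mean of at least 50 counts, and all 3 are reported. Statements on counting error cover that error only.

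The main test was tested on simulated data for this comparison. Counts were drawn from the recovered means with added variation between libraries, in 5 sets with 200 changed genes each, over 19531 to 19663 tested genes. The size of that variation is not known from 2 libraries per group, and the result depended on it. The 7 settings of the variation were looked at one after another with their results in view, and some with a chi-square form were dropped because the simulated values broke down. Over the 7 settings, the share of changed genes with at least 10 TPM that was called ran from 0% to 76.1% at 1.5-fold, from 3.03% to 96.9% at 2-fold, from 74.8% to 100% at 4-fold and from 90.2% to 100% at 8-fold. Between 3.92% and 16.6% of all calls were false, where 5% was aimed at. The simulated variance of the crossed split was between 0.92 and 2.74 times the real one, and the lowest shares called at 2-fold came from the setting at 2.74 times. In the 3 settings nearest to the real variance of 0.0170 (0.0157, 0.0176 and 0.0211), 96.9%, 83.6% and 65.2% were called at 2-fold, and 16.6%, 5.01% and 8.04% of calls were false. In the 2 settings whose total degrees of freedom spanned the 5.83 of the real libraries, 65.2% and 66.7% were called at 2-fold and 8.04% and 5.23% of calls were false. The false share of voom's calls ran from 7.69% to 30.2%. The test was therefore not shown to hold its error rate at every noise level, and its power is uncertain. The shares called hold for 200 changed genes per set, and fewer changed genes would make the adjusted p harder to pass.

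The alternatives fixed before the data were examined were the fit without the block, pseudocounts of 0.1 and 5, no filter and a filter at 5 TPM, rescaling to a median log2 ratio of 0, quantile normalization, moderation without trend or robust, other call thresholds, and each library left out in turn without the block. The fits with voom and with crossed replicate numbers, the count of large differences with its level limits, and the limit of 10 counts for IDs at 0 in one group were chosen after the data were seen.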

Results

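RNA sequencing compared planarian tail tissue after RNA interference (RNAi) against nsf with tail tissue after EGFP RNAi. The symbol nsf usually stands for N-ethylmaleimide-sensitive factor, an ATPase that takes SNARE complexes apart after membrane fusion and so serves vesicle traffic and secretion. EGFP is a jellyfish fluorescent protein with no counterpart in planarians, and its dsRNA was the control. The series is about neuroendocrine control of planarian regeneration, and this comparison asks how the transcript profile differs once nsf is targeted. There were 2 libraries per group. Each library had between 24844 and 25355 of the 36019 IDs above 0 TPM, and the counts recovered from the TPM summed to between 7010071 and 9834847 per library.

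The tail profiles of the 2 groups were close to each other. Across the 19555 IDs with a mean of at least 1 TPM, Spearman's rho was 0.986 between the EGFP RNAi libraries and 0.983 between the nsf RNAi libraries. Between groups, it was 0.975 and 0.978 for libraries with the same replicate number and 0.984 and 0.983 for libraries with different numbers. These correlations are across genes, which are not independent replicates. The first principal component held 46.4% of the variance between libraries and placed both EGFP RNAi libraries (-24.2 and -16.8) apart from both nsf RNAi libraries (26.7 and 14.4). The second held 38.0% and placed EGFP RNAi replicate 1 and nsf RNAi replicate 2 opposite the rest. In these batch-adjusted values the split by replicate number was narrower than the group and crossed splits. That tends to make libraries with the same number the least alike. It also leaves the group and crossed splits as the first and second components, so neither pattern can be read as an effect of the group alone. Recovered counts of the EGFP RNAi pair and of the nsf RNAi pair differed by more than sampling noise, with a chi-square per degree of freedom of 1.71 and 1.40. These values cannot tell separate samples from repeated library preparations of 1 sample. All 4 libraries were kept as separate samples, as labelled.

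One transcript passed the test, and it was lower after nsf RNAi. SMED30019484 fell from 87.4 ± 1.67 TPM in EGFP RNAi to 35.4 ± 1.24 TPM in nsf RNAi (SD, n = 2 each), which is 2.47-fold lower in nsf RNAi. Its log2 fold change was -1.28 with a standard error of 0.07 and a limma adjusted p of 0.043. The counts recovered for it were 1101 and 1566 in the EGFP RNAi libraries and 427 and 503 in the nsf RNAi libraries, over a recovered length of 2372. No ID was called higher in nsf RNAi by this test, while voom on recovered counts called between 6 and 61 higher, depending on its count filter and block. At an unadjusted p under 0.05, limma counted 1265 IDs, 766 of them higher and 499 lower, where calibrated p-values would give 978 without any difference. In a limma fit without the block, the crossed split (EGFP RNAi replicate 1 with nsf RNAi replicate 2 against the rest) reached 1489, and the real split 2170. The residual of such a fit includes the narrow split by replicate number, which can raise both counts. The 1489 therefore cannot tell whether the excess in the 1265 belongs to the group. The call of SMED30019484 was lost at a pseudocount of 0.1 (limma adjusted p = 0.052), at a mean of at least 5 TPM (adjusted p = 0.086), without the abundance trend (adjusted p = 0.80) and when nsf RNAi replicate 1 or 2 was left out (adjusted p = 0.14 and 0.22). Over its 20 alternatives the log2 fold change stayed between -1.32 and -1.19 and the limma adjusted p ran from 5.7e-58 to 0.80. The lowest adjusted p came from voom with the replicate block and no count filter. That fit was chosen after the data were seen and called 123 IDs.

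Among IDs with a mean of at least 10 TPM, the largest differences in the other direction belonged to SMED30001888 and SMED30006533, and neither passed the test. SMED30001888 stood at 1.05 and 6.57 TPM in EGFP RNAi replicates 1 and 2 and at 121 and 72.8 TPM in nsf RNAi replicates 1 and 2. The group means were 3.81 ± 3.90 and 96.8 ± 34.0 TPM (SD, n = 2 each), a ratio of 25.4. Its log2 fold change was 4.59 with a standard error of 0.55 and a limma adjusted p of 0.53. The recovered counts were 3 and 26 against 335 and 226. SMED30006533 was at 29.6 ± 4.06 TPM in EGFP RNAi and 208 ± 60.5 TPM in nsf RNAi (SD, n = 2 each), a ratio of 7.03. For it the log2 fold change was 2.75 with a standard error of 0.19 and a limma adjusted p of 0.087, and the recovered counts were 113 and 190 against 1027 and 759. Without the replicate block, SMED30006533 passed the test (limma adjusted p = 0.047) and SMED30001888 did not (adjusted p = 0.143). That fit counts 1 residual degree of freedom more, which is too many if the batch taken out was the replicate number. Over the alternatives the limma adjusted p of SMED30006533 ran from 4.2e-106 to 0.83 and that of SMED30001888 from 3.0e-23 to 0.83. The lowest value of each came from voom with the replicate block and no count filter, a fit chosen after the data were seen. The log2 fold change of SMED30001888 was 3.65 without EGFP RNAi replicate 1 and 5.53 without EGFP RNAi replicate 2.

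The second ID named for a lower level in nsf RNAi, SMED30005967, did not pass the test either. It was at 35.6 ± 2.93 TPM in EGFP RNAi and 20.8 ± 1.32 TPM in nsf RNAi (SD, n = 2 each), and its log2 fold change was -0.75 with a standard error of 0.09 and a limma adjusted p of 0.53. Its recovered counts were low, at 54 and 84 against 31 and 38.

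**Figure D1:**
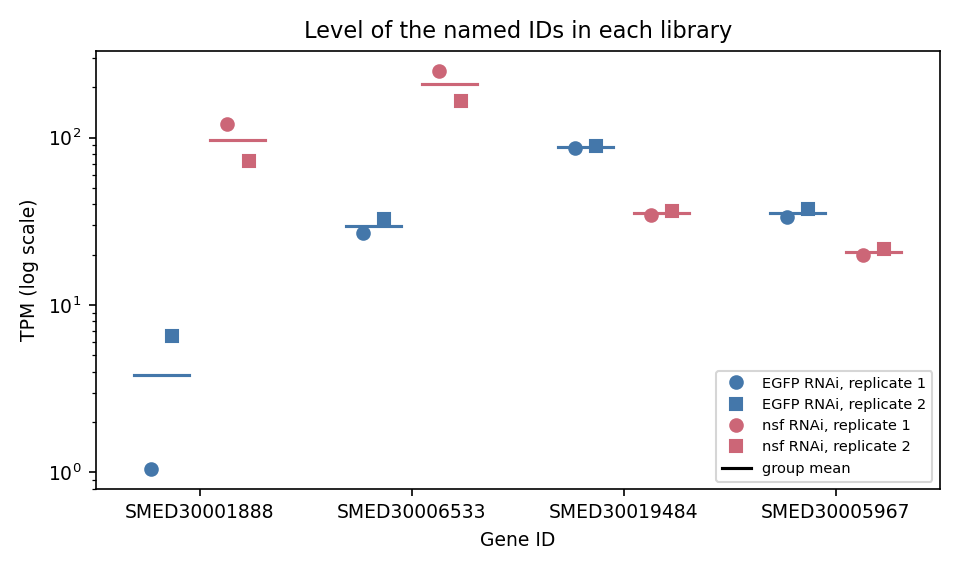
TPM (log scale) of the 4 named gene IDs in each of the 4 libraries, with circles for replicate 1, squares for replicate 2 and a line at each group mean. SMED30001888 and SMED30006533 lie higher in both nsf RNAi libraries than in both EGFP RNAi libraries, SMED30019484 and SMED30005967 lie lower, and of these 4 only SMED30019484 passed the test (limma adjusted p = 0.043).

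Large differences were rare among well-measured transcripts. Of the 10557 IDs with a mean of at least 10 TPM, 5 differed by more than 2-fold between the groups on the log2(TPM + 1) scale. Of these, 4 were higher in nsf RNAi and 1 was lower. They include SMED30001888, SMED30006533 and SMED30019484, and the other two had log2 fold changes of 1.02 and 1.01. When the same libraries were split the crossed way, with EGFP RNAi replicate 1 and nsf RNAi replicate 2 on one side, 1 ID exceeded 2-fold. That ID was SMED30001888, whose EGFP RNAi libraries differ from each other. For 10518 of the 10557 IDs (99.6%), the 95% confidence interval of the fold change lay within 2-fold in either direction, and the median half-width of the interval was 0.24 on the log2 scale. These intervals rest on the moderated spread of the crossed split, from 2 libraries per group. In simulation the test called from 3.03% to 96.9% of 2-fold changes at this level, depending on the spread assumed between libraries. In the 3 settings nearest to the real variance of the crossed split, it called 96.9%, 83.6% and 65.2% at 2-fold. At 1.5-fold it called 76.1%, 38.4% and 14.2%. The 2 settings whose total degrees of freedom spanned that of the real libraries called 65.2% and 66.7% at 2-fold. At 1.5-fold these 2 settings called 14.2% and 12.6%. All these shares hold for 200 changed genes per set. Changes of 2-fold and less could therefore be missed, and SMED30001888 and SMED30006533 did not pass despite larger differences.

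**Figure D2:**
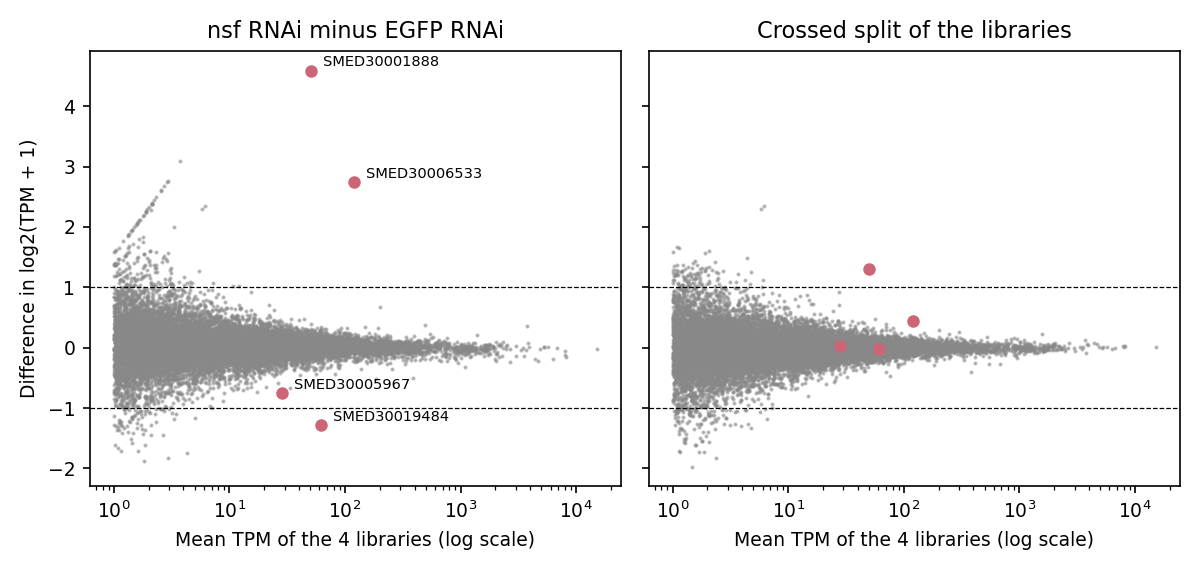
Difference in log2(TPM + 1) against mean TPM (log scale) for each of the 19555 tested IDs, shown for nsf RNAi minus EGFP RNAi (left) and for the crossed split, EGFP RNAi replicate 2 with nsf RNAi replicate 1 minus the other two libraries (right). Dashed lines mark 2-fold, and red points are the 4 named IDs. Above 10 TPM, 5 IDs lie outside the lines on the left and 1 on the right.

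The spread of differences depended on transcript level. Among the 1571 IDs at 100 TPM or more, the SD of the log2 difference between groups was 0.11, against 0.07 for the crossed split. Among the 6383 IDs at 1 to 5 TPM these SDs were 0.45 and 0.42. The groups did not overlap for 8654 of the 19555 IDs (44.3%). Chance gives 33.3% where all splits of the 4 libraries vary alike, which is not so in these batch-adjusted values, since the split by replicate number was narrower than the others. With no group difference and the spreads of the crossed and replicate splits, 40.4% would be apart, and in the crossed split 7417 IDs (37.9%) were. An ID apart in 1 split cannot be apart in another, so the 37.9% is not independent of the 44.3%. Of the 8654, 5522 were higher in nsf RNAi and 3132 were lower, or 63.8% higher. After each library was rescaled to a median log2 ratio of 0, which removed a median shift of 0.03 and by its construction brings the split near even, 4187 were higher and 4243 lower, or 49.7% higher.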

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

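The fits with voom and with crossed replicate numbers, and the count of large differences with its level limits, were chosen after the data were seen. The count of called IDs, 1 as reported, was 3 with no replicate block, 2 without a filter, 2 with quantile normalization and 2 at an adjusted p under 0.1. It was 0 at a pseudocount of 0.1, 0 at a mean of at least 5 TPM and 0 without the trend. The cause was not tested. Of the 3 IDs called with no replicate block, 1 was at 0 in both EGFP RNAi libraries. Leaving out one library, without the block, gave counts between 0 and 48, at 48 and 46 without EGFP RNAi replicate 1 or 2 and 0 without nsf RNAi replicate 1 or 2. There the lone library of a group is assumed to vary like the other group, and 19 of the 48 and 19 of the 46 were at 0 in both EGFP RNAi libraries. Voom depended on its count filter. With the replicate block it called 123 IDs with no filter, 26 at a mean of at least 10 counts and 18 at 50, and without the block 31, 17 and 13. Of the 26, 21 changed by less than 1.5-fold, and voom made many false calls in simulation. A crossed replicate block called 31, of which 21 were at 0 in both EGFP RNAi libraries, so the count depends on which libraries are taken to have shared a batch. That block leaves the split by replicate number as its only residual. The variance of this split was 0.60 times that of Poisson counts at 1 to 5 TPM and 2.30 times at 100 TPM or more. A residual narrower than counting noise can make p-values too small, so the 31 are not an equal alternative to the 1 reported. The 4 named IDs kept their direction in the 20 alternatives run on each. SMED30019484 was called in 15, SMED30006533 in 12, SMED30001888 in 9 and SMED30005967 in 2. These counts pool the alternatives fixed beforehand with the voom fits and the crossed block. Each of those later fits called SMED30019484, SMED30006533 and SMED30001888. Among the alternatives fixed beforehand, SMED30001888 and SMED30005967 were called only when an EGFP RNAi library was left out, which leaves 1 library in that group. The IDs over 2-fold apart numbered 11 at a mean of at least 5 TPM, where the crossed split had 8, and 3 at 20 TPM, where it had 1. The mean Spearman correlation, 0.981, was 0.953 with no filter and 0.987 at 5 TPM. The level of nsf and the gene lists gave no value to vary, and there were no negative values to leave out. Depth limits low IDs most: simulated counting error alone gave the crossed split an SD of 0.34 at 1 to 5 TPM and 0.04 at 100 TPM or more.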

Other observations

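The test of the crossed split, the test of shifts across level classes, all tests of the spread between the nsf RNAi libraries and the limit of 10 counts used there were chosen after the result was seen. The other tests were set out before their results were known.

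Once the libraries were rescaled to a median log2 ratio of 0, the lean of the IDs varied with their level. Among IDs at 100 TPM or more whose groups did not overlap, 531 were lower and 232 higher, so that 30.4% were higher. The class at 1 to 5 TPM leaned the other way, with 1494 higher and 1237 lower (54.7% higher), and those at 5 to 20 and at 20 to 100 TPM had 49.7% and 50.1% higher. As deposited, every class leaned higher, with 62.7%, 61.8%, 68.6% and 57.6% higher from the lowest class to the highest. The class at 100 TPM or more then had 314 lower and 427 higher. At an unadjusted p under 0.05 in limma, this class held 107 lower and 75 higher IDs as deposited.

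There were 5 IDs with a mean of at least 10 TPM that differed by more than 2-fold between the groups. Spread between libraries unrelated to the group stays open as a cause of this number. The crossed split had 1 such ID against 5, and 1 against 3 at a mean of at least 20 TPM, but 8 against 11 at 5 TPM. Counting noise is argued against by simulation, since 0 of 100 simulated sets without a group difference reached 5 and the highest had 2. As for scaling of the libraries, 3 of the 5 stayed over 2-fold after rescaling, and those that did not had log2 fold changes of 1.02 and 1.01 before it. A response to nsf RNAi is a hypothesis that stays open and was not tested further, beside differences between cultures that share a group.

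Among IDs whose groups did not overlap, 63.8% were higher in nsf RNAi. The share of 49.7% after rescaling decides nothing about the cause, because centring brings it near even whatever made the lean. On the log2(TPM + 1) scale, scaling of the libraries would shift low IDs least, whereas the median difference between groups was larger at 1 to 5 TPM than at 100 TPM or more (0.06 against 0.01, a gap of 0.054). This goes against 1 common factor per library as the whole cause. The split by replicate number had a gap of 0.035 in size, however, so scaling was left open. Because each TPM column sums to the same total, a fall of abundant transcripts would raise all others and could give such a gap too. The gap therefore cannot tell a small rise of many transcripts after nsf RNAi from a fall of abundant ones. Both stay open and were not tested.

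A set of 64 IDs had 0 TPM in both EGFP RNAi libraries and 10 or more recovered counts over the nsf RNAi libraries, with counts in both, against 3 IDs for the reverse, none of the 64 above a mean of 3.74 TPM. This imbalance depended on the limit and turned without one, with 309 against 409 IDs at any level above 0, 205 against 162 at 4 counts, 91 against 24 at 8 and 41 against 0 at 15. Counting noise is argued against, since 0 of 100 simulated sets reached 64. Adjustment of low counts by the authors predicted nsf RNAi libraries that agree more closely than Poisson counts, and over all 64 IDs this was not met, with a spread of 1.37 times that of Poisson counts where 100 draws gave 0.58 to 1.47. The 55 IDs with 2 or more counts in both nsf RNAi libraries were a part singled out after the counts were seen. Their spread was 0.338, where 100 draws under the same condition gave 0.61 to 1.61. For comparison, 3804 IDs of like counts above 0 in both EGFP RNAi libraries gave 0.909. The prediction was met in these 55, so such an adjustment may have acted on them. Agreement between the nsf RNAi libraries does not show why the EGFP RNAi libraries were at 0, so the source of the imbalance stays open. The 9 IDs with a count of 1 in 1 nsf RNAi library (7.68, draws 7.04 to 8.47) decide nothing. A response to nsf RNAi stays open.

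Over the 10555 IDs with recovered counts and at least 10 TPM, the variance of log2 differences was 2.05 times that of Poisson counts between the groups and 1.56 times for the crossed split. Between replicate numbers 1 and 2 it was 0.715 times, below the 0.95 to 1.05 that 100 simulated sets gave. At 100 TPM or more all 3 were above Poisson counts, at 6.87 times between the groups, 2.49 times for the crossed split and 2.30 times between replicate numbers. In a limma fit without a block, IDs with an unadjusted p under 0.05 numbered 2170 for the real split, 1489 for the crossed split and 167 for the split by replicate number, with 3, 0 and 0 calls. Each such fit takes the other splits as its residual, so the narrow split by replicate number can raise the first and second of these counts.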
